A study of Rattus norvegicus with 3 samples.

How the data were processed

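Messenger RNA was sequenced from the motor cortex of 3 male Sprague-Dawley rats with cerebral ischemia and reperfusion, a loss of blood supply to the brain followed by its return. The rats carry the numbers 19, 35 and 70, and all are labelled 8 weeks. The labels do not say whether this is the age or the time after the operation. They form 1 group, and no control group was analysed here. The libraries were taken as separate animals because the labels give each its own animal number.

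The deposited values are FPKM, fragments per kilobase of gene per 1000000 fragments. Per the design text in the labels, the authors counted the fragments of each gene, normalized them and calculated FPKM with a Perl script. How they normalized is not given in the sources used here. HISAT2 2.0.4, StringTie 1.3.0 and the genome build Rnor 6.0 are named in the submitters' processing notes, without their roles. Each file lists 30957 Ensembl genes with symbol and position, and all coordinates in the text are those of the files. FPKM was used as deposited, since fragment counts were not used here and a count model would not fit these values.

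Depth was read from the low values. Where whole fragments are counted, the ratio of a gene's FPKM between 2 rats is a ratio of whole numbers times a constant. Of the genes under 0.2 FPKM in both rats of a pair, 89.07% (rats 19 and 35), 90.41% (19 and 70) and 88.54% (35 and 70) lay within 0.5% of a ratio of whole numbers up to 8. Random ratios did so in 7.94%, 7.62% and 8.07%. On this scale 1 fragment on a gene of 1 kb was worth 0.06427, 0.06075 and 0.06231 FPKM in rats 19, 35 and 70. This corresponds to 15560000, 16460000 and 16050000 fragments after the authors' normalization, so that 1 FPKM on a gene of 1 kb rests on about 16 fragments in each rat. The length by which a gene's fragments were divided was recovered as the shortest one up to 20000 bp that gave whole fragments in all 3 rats, within 0.005. Of 14071 genes above 0 in every rat and at a mean FPKM of 1 or more, 14060 had such a length, against 1.88% after random changes of the values. In 178 of them the length exceeded the gene's span and is doubtful. Exact zeros can be failed estimates, because genes used by every cell (Hprt1, Rps6, Rpl8, Hsp90aa1) were listed at 0 in all rats.

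Values were analysed as log2(FPKM + 1), which understates differences of low genes, over the 14134 genes with a mean FPKM of 1 or more. With 1 group there is no test between groups, and each rat's own value is given with the mean and SD over 3 rats. For each of 47 gene lists, the deviation of a rat is the median over the members of log2(FPKM + 1) minus that gene's mean over the 3 rats. It was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A value is called outside when it lies beyond the central 95% of these. This describes the 3 libraries and is not a test, since the members of a list vary together and random genes do not. Lists with fewer than 5 members at a mean FPKM of 1 were left out of this step. Ratios of 18 gene pairs were tested with the two-sided exact sign-flip permutation test over 3 rats, whose smallest possible p is 0.25. On simulated libraries of 14134 genes with noise of SD 0.4, lists of 12 genes were called outside in 7.5% of cases with no shift, 72.5% at a shift of 0.5 and 100.0% at 1.0 (log2). The simulated noise was independent between genes, so these rates do not carry over to lists whose members vary together.

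The lists, the pairs, the tests of the report and the alternatives, but not the further tests and lists of the closing section, were chosen before the data were examined. So was the rule for named genes: the 10 with the highest mean FPKM, the 20 named genes with the largest SD of log2(FPKM + 1) among those with a mean FPKM of 5 or more, both genes of each pair, and in each list the members with the highest mean FPKM and, where a rat lay outside, those with the largest SD, with further members where a count needed them. Choices made after the data were seen are the exclusion of clone-based and locus names from the 20 genes, the use of the row with the highest mean FPKM where a symbol stands on several rows, the highest minus lowest list deviation as a measure of spread, the recovery of depth and gene lengths, the closing section's tests of scaling, gene length, the glial lists, the meninges and the choroid plexus, and its 5 further lists, set out before their members' values were looked at. Some genes that the rule takes are not reported here. Genes of families with near-identical copies (RT1, ribosomal and hemoglobin genes) are uncertain, because the authors' counting could split or drop shared fragments.

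The alternatives were a pseudocount of 0.1, FPKM minima of 0.5 and 5 or none, rescaling each library to a sum of 1000000, median-of-ratios scaling, leaving out mitochondrial or hemoglobin genes, and leaving out each rat in turn. Rescaling to a sum of 1000000 raised the median gene by 0.80, 0.85 and 0.96 (log2) in rats 19, 35 and 70, or by -0.06, -0.02 and 0.09 with the mean of the 3 sums kept, and median-of-ratios scaling moved it by -0.04, -0.05 and 0.09. In the closing section, 5 further lists were used; intervals there come from 10000 bootstrap resamples of list members, and 1 test matched random lists on expression (10 bins) and recovered length (5 bins). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.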

Results

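The transcriptome of the motor cortex was measured in 3 rats after cerebral ischemia and reperfusion, at an effective depth of 15560000, 16460000 and 16050000 fragments in rats 19, 35 and 70. Throughout, values for 3 rats are FPKM in the order 19, 35 and 70 unless another order is given. Transcripts of the Y chromosome were present in each rat, with Eif2s3y at 48.7, 38.9 and 38.6 and Ddx3y at 27.0, 30.8 and 27.0, as the male label requires. Counting genes at 1 FPKM or more gave 14082, 13554 and 13696 (13777 ± 273, SD, n = 3), and 12479 genes reached this level in all rats.

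The comparison that the design allows is between the 3 rats of the group, and it asks how alike their cortex transcriptomes were. Transcripts of neurons differed most. The 11 pan-neuronal markers had a median of 60.8, 3.75 and 83.0 FPKM, a 22.1-fold range (49.2 ± 40.9, SD, n = 3), and all 11 were lowest in rat 35. Snap25, which encodes a protein of synaptic vesicle fusion (chromosome 3, 129599353 to 129788400, Rnor 6.0), was at 383, 12.2 and 564 FPKM. Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons (chromosome 1, 101161372 to 101173195), was at 324, 12.2 and 383. The list deviations from the 3-rat mean were 0.98, -2.42 and 1.88 (log2) for pan-neuronal markers, 0.67, -2.10 and 1.21 for excitatory neurons and 0.87, -1.81 and 0.44 for inhibitory neurons, all outside the central 95% of matched random lists. The inhibitory value of rat 70 depended on the processing: it was 1.31 with a pseudocount of 0.1 and 1.26 at a mean FPKM of 5 or more, both above rat 19 (1.15 and 0.92), and 0.68 after rescaling to a common sum. Among inhibitory markers, the order of the rats differed by gene. Sst, which encodes somatostatin, was at 205, 13.8 and 45.0, and Pvalb, which encodes parvalbumin, at 17.8, 4.41 and 75.5. Without rat 35, the highest minus lowest deviation went from 4.30 to 0.63 for pan-neuronal, from 3.31 to 0.24 for excitatory and from 2.68 to 0.22 for inhibitory markers.

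Genes of the synapse followed the same order of rats. Of 29 synaptic protein genes, 28 were lowest in rat 35 and 25 highest in rat 70, with list deviations of 0.61, -2.22 and 1.45. Syp (synaptophysin) was at 276, 12.5 and 440, Syt1 at 183, 7.79 and 284, and Camk2a, the calcium- and calmodulin-dependent kinase of excitatory synapses, at 129, 13.4 and 459. All 22 glutamate receptor genes were lowest in rat 35 (0.59, -1.45 and 1.05), among them Grin1, the obligate NMDA receptor subunit, at 39.96, 1.79 and 66.7. The 15 GABA receptor genes did so too (0.57, -2.14 and 1.60), with Gabbr1 at 55.9, 13.9 and 72.6. Neurotransmitter and chloride transporters deviated by 0.04, -1.36 and 1.08, the first of these inside the random range. Without rat 35, the highest minus lowest deviation went from 3.67 to 0.63 for synaptic proteins, from 2.497 to 0.34 for glutamate receptors, from 3.74 to 0.89 for GABA receptors and from 2.43 to 0.77 for transporters. Leaving out rat 70 brought the transporters to 1.53.

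**Figure D1:**
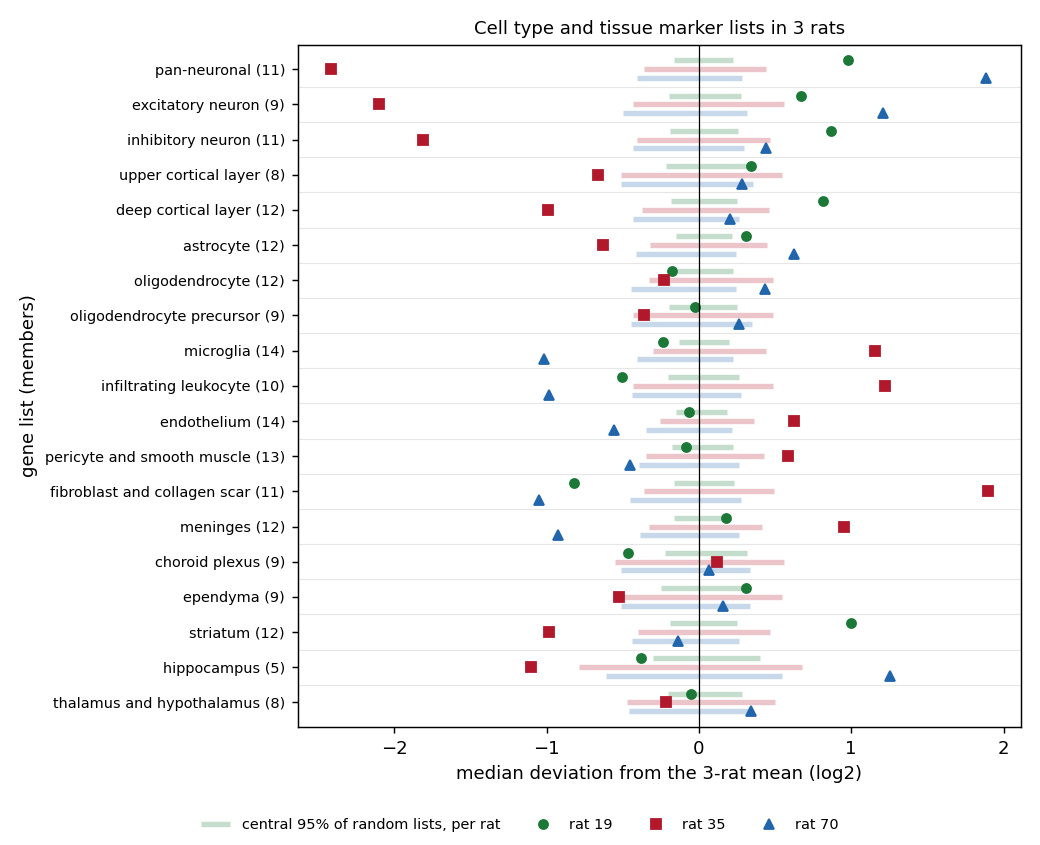
Deviation of 19 cell type and tissue marker lists from the 3-rat mean. Each point is one rat's median over the list's members of log2(FPKM + 1) minus the gene's mean over 3 rats, with the number of members in parentheses, and the pale line of the same colour spans the central 95% of random lists matched on expression. Rat 35 has the lowest value for pan-neuronal markers (-2.42) and the highest for fibroblast and collagen scar genes (1.90).

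Phagocyte, complement and collagen transcripts ran in the opposite direction. Of 20 genes of phagocytic microglia, 19 were highest in rat 35, and the list deviated by -0.63, 1.499 and -0.81. Spp1, which encodes osteopontin (chromosome 14, 6673686 to 6679901), was at 224, 4161 and 126 FPKM. Gpnmb was at 140, 1477 and 228, the lysosomal protease gene Ctsd at 697, 3576 and 466, the lysozyme gene Lyz2 at 184, 2231 and 369, and Apoe at 2289, 7439 and 2453. Of the 11 fibroblast and collagen genes measured, all were highest in rat 35 (-0.82, 1.90 and -1.05), with Col3a1 at 81.7, 1086 and 68.3 and Col1a1 at 72.8, 754 and 80.6. General microglia markers were highest in rat 35 for 14 of 14 tested genes (-0.23, 1.16 and -1.02), and complement genes for 17 of 19 (-0.39, 1.19 and -0.72), with C1qa in both lists at 310, 761 and 300. Without rat 35, the highest minus lowest deviation went from 2.31 to 0.11 for phagocytic microglia, from 2.95 to 0.26 for collagen genes, from 2.17 to 0.85 for microglia and from 1.90 to 0.39 for complement, and without rat 70 that of microglia was 1.29.

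**Figure D2:**
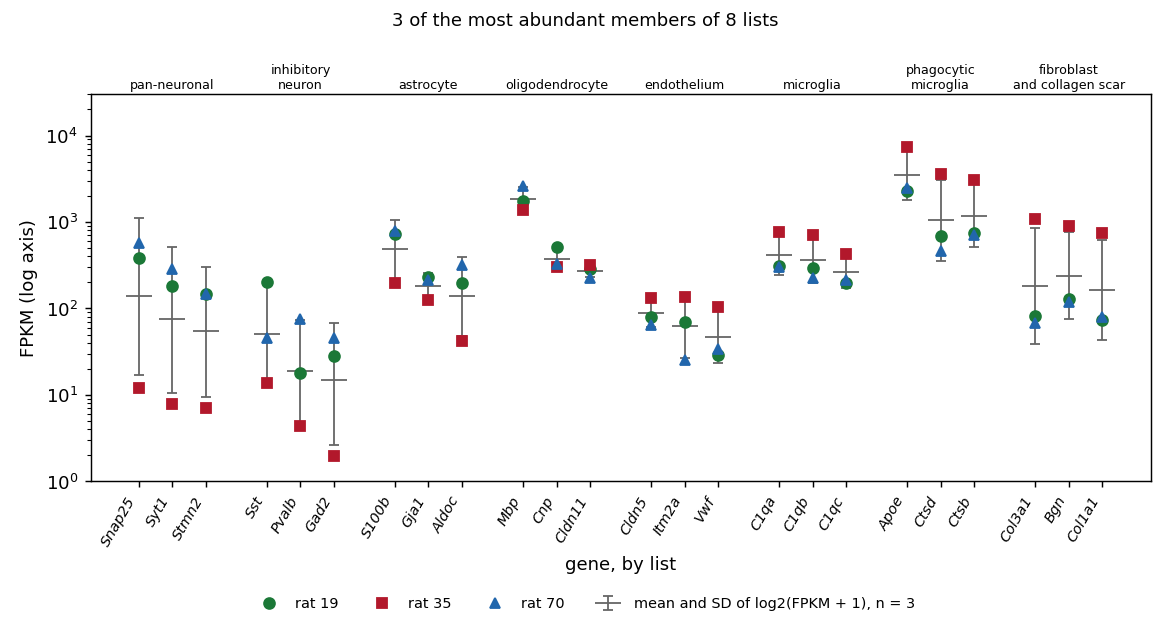
FPKM of 3 of the most abundant members of each of 8 lists in each rat, on a log axis. Points are the 3 rats, and the horizontal bars and whiskers are the mean and SD of log2(FPKM + 1) over them, drawn back on the FPKM scale. Rat 35 is lowest for Snap25 (12.2) and highest for Col3a1 (1086), while the oligodendrocyte genes shown here, but not all of their list, lie close together, with Mbp between 1392 and 2591.

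Leukocyte, cytokine and antigen presentation genes were also highest in rat 35. Markers of infiltrating leukocytes deviated by -0.51, 1.22 and -0.99, with S100a9, a calcium-binding protein gene of neutrophils and monocytes, at 0.61, 77.4 and 2.83 and Cd8a at 6.30, 46.4 and 4.22. Cd8b followed Cd8a (1.75, 13.8 and 1.23), but the T cell genes Cd3e (0.43, 1.35 and 0.36) and Cd3d (0.71, 0.93 and 0) stayed low. The values of Cd8a therefore do not by themselves show T cells. Cytokines and chemokines deviated by -0.23, 1.13 and -0.74. Ccl2, a chemokine that attracts monocytes, was at 4.16, 40.2 and 5.89, whereas Cx3cl1, the neuronal fractalkine, was at 88.2, 73.9 and 103. Antigen presentation genes deviated by 0.21, 0.92 and -1.01, and all 19 that reached 1 FPKM in any rat were lowest in rat 70, among them Cd74 at 59.0, 159 and 10.9 and B2m at 640, 1099 and 361. Pyroptosis and necroptosis genes deviated by 0.04, 0.88 and -0.83, the first inside the random range. Interferon response genes had another order, 0.44, 0.20 and -0.52, with rat 35 inside the random range and Mx1 at 45.9, 18.2 and 12.7. With rat 35 left out, the highest minus lowest deviation of the leukocyte, cytokine and antigen presentation lists went from 2.21, 1.87 and 1.93 to 0.30, 0.39 and 0.95, and with all detected members that of the leukocyte list was 1.10, with rat 35 at 0.57 (1.84 at a mean FPKM of 5 or more). The calls of rat 19 ended for leukocytes with all detected members (-0.07) and for cytokines (-0.12) and antigen presentation (0.06) at a mean FPKM of 5 or more. Without rat 70, the highest minus lowest deviation of the cytokine, antigen presentation, pyroptosis and interferon lists was 1.20, 0.78, 0.99 and 0.11, the latter pair from 1.71 and 0.96.

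Astrocyte and oligodendrocyte lists did not share one order of the rats. Astrocyte markers deviated by 0.31, -0.63 and 0.63, and the spread depended on the gene: S100b was at 721, 195 and 793, while the water channel gene Aqp4 was at 113, 54.6 and 16.9. Genes of astrocyte reactivity deviated by -0.09, 0.77 and -0.78, with rat 19 inside the random range. The order differed within this list, since the intermediate filament gene Gfap was highest in rat 19 (1878, 564 and 688) and Vim in rat 35 (687, 1398 and 438). Oligodendrocyte markers deviated by -0.18, -0.23 and 0.43, with rat 35 inside the random range, and the myelin gene Mbp was at 1736, 1392 and 2591. Oligodendrocyte precursor markers lay inside the random range in all rats (-0.03, -0.36 and 0.26). Leaving out rat 35 took the highest minus lowest deviation of the astrocyte and reactivity lists from 1.26 and 1.55 to 0.54 and 0.62, and leaving out rat 70 took that of the reactivity and oligodendrocyte lists to 0.81 and 0.25, the latter from 0.66.

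Vascular and meningeal genes were highest in rat 35. Endothelial markers deviated by -0.06, 0.63 and -0.56, pericyte and smooth muscle markers by -0.09, 0.58 and -0.46 (rat 19 inside the random range in both), and meningeal markers by 0.18, 0.95 and -0.93, again with rat 19 inside. Cldn5, a tight junction gene of brain endothelium, was at 80.3, 131 and 63.7. Pdgfrb, a receptor gene with the largest SD of the pericyte list, was at 21.8, 102 and 18.4. The other members of that list differed less, with Vtn at 17.9, 20.9 and 11.7. The most abundant meningeal marker, Ptgds, did not follow its list (1193, 1152 and 776). Hemoglobin genes were too few for a list deviation, with Hba1 at 19.1, 84.8 and 26.0. Markers of the choroid plexus deviated by -0.47, 0.12 and 0.07, with only rat 19 outside, and those of the ependyma by 0.31, -0.53 and 0.16, with none outside, although rat 35 was outside after rescaling to a common sum (-0.65), with a pseudocount of 0.1 (-1.003) and with all detected members (-0.43), as was rat 19 with the latter (0.27). Leaving out rat 35 brought the highest minus lowest deviation of endothelium, pericytes and meninges from 1.19, 1.04 and 1.88 to 0.48, 0.35 and 0.72, and leaving out rat 70 brought endothelium and meninges to 0.61 and 0.68. The call of rat 70 for pericytes ended at a mean FPKM of 5 or more (-0.45). The choroid plexus range of 0.59 was 0.03 without rat 19 and 0.24 with all detected members.

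Markers of cortical layers and of neighbouring regions were spread unevenly over the rats. Deep-layer genes deviated by 0.81, -0.99 and 0.20 and upper-layer genes by 0.34, -0.66 and 0.28, with rat 70 inside the random range in both. With a pseudocount of 0.1, rat 70 was outside for deep-layer genes (0.44) and rat 35 was at -1.53. Striatal markers were highest in rat 19 (0.997, -0.98 and -0.14, rat 70 inside), with the enkephalin gene Penk at 51.1, 6.06 and 6.28. Hippocampal markers deviated by -0.38, -1.10 and 1.251, on 5 measured genes, and no rat was outside when all detected members were counted (-0.07, -0.02 and 0.03, a range of 0.11 in place of 2.36). In this list, C1ql2 was at 2.17, 0.18 and 28.7 and Prox1, a transcription factor gene of dentate granule cells, at 2.33, 1.80 and 10.2. Thalamic and hypothalamic markers were inside the random range (-0.05, -0.22 and 0.34), but rat 70 was outside at a mean FPKM of 5 or more (0.57), and Prkcd was at 18.1, 42.7 and 153. Without rat 35, the highest minus lowest deviation of the deep-layer, upper-layer and striatal lists went from 1.81, 1.01 and 1.98 to 0.31, 0.04 and 0.94; without rat 19 that of the deep-layer and striatal lists was 1.13 and 0.99, and without rat 70 that of the hippocampal list was 0.74. With all detected members the striatal range was 1.01, and rat 19 was no longer outside for upper-layer genes (0.21), nor was it after rescaling to a common sum (0.19).

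Genes of growth and metabolism differed less than neuronal genes. Neurogenesis and proliferation genes deviated by 0.04, 0.89 and -0.83 (rat 19 inside the random range), with the proliferation marker Mki67 at 5.61, 15.7 and 1.41 and the transcription factor gene Sox2 at 67.0, 13.2 and 28.0. Axon growth genes and their inhibitors deviated by 0.14, -0.44 and 0.17 (rat 19 inside), and Gap43, which encodes a growth cone protein, was at 189, 14.7 and 101. The list of neurotrophins and growth factors lay inside the random range in all rats (-0.05, 0.01 and 0.04), with rat 70 outside at a pseudocount of 0.1 (0.27), yet Igf1 was at 5.68, 56.0 and 4.16. Glycolysis genes deviated by 0.21, -0.67 and 0.48, and 14 of 16 were lowest in rat 35. Genes of the respiratory chain encoded in the nucleus deviated by 0.02, -0.16 and 0.12 (rat 70 just outside), and the mitochondrially encoded ones by 0.40, -0.36 and -0.04 (rat 70 inside). Cytosolic ribosomal protein genes were highest in rat 35 for 35 of 36 tested genes (-0.05, 0.55 and -0.50, rat 19 inside). Leaving out rat 35 took the highest minus lowest deviation of the proliferation, axon growth, glycolysis and ribosomal lists from 1.72, 0.61, 1.14 and 1.05 to 1.04, 0.01, 0.34 and 0.44, and leaving out rat 70 took the proliferation and ribosomal lists to 0.79 and 0.62. For the nuclear and mitochondrial respiratory chain lists it went from 0.28 and 0.76 to 0.13 and 0.46 without rat 35, to 0.15 for the nuclear list without rat 70 and to 0.26 for the mitochondrial list without rat 19. After rescaling to a common sum and by the median of ratios, rat 19 was outside for axon growth genes (0.17 and 0.18) and rat 70 was at 0.33 and 0.32. The axon growth range was 0.93 at a mean FPKM of 5 or more, where rat 70 was at 0.41, with all detected members rat 35 was at 0.54 for proliferation genes, and after median-of-ratios scaling the nuclear respiratory chain range was 0.43, with rat 70 at 0.22.

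Stress lists had rats outside the random range in some cases only. Hypoxia response (-0.05, 0.21 and -0.05), antioxidant defence (-0.06, 0.18 and -0.11), autophagy and mitophagy (0.01, -0.14 and 0.03) and the reference genes (-0.01, 0.32 and -0.25) were inside the random range in every rat. Being inside does not show that the rats were alike, and single genes differed: the heme oxygenase gene Hmox1 was at 34.7, 131 and 22.6, the glutathione peroxidase gene Gpx1 at 127, 552 and 90.2 and Actb at 1675, 3160 and 1344. Apoptosis genes deviated by -0.14, 0.46 and -0.45, all outside. Ferroptosis and iron genes deviated by -0.20, 0.34 and -0.14 (only rat 19 outside), and the ferritin heavy chain gene Fth1 was at 2646, 2720 and 2428 while the light chain gene Ftl1 was at 403, 1124 and 197. Heat shock and unfolded protein genes deviated by 0.11, 0.38 and -0.45 (only rat 70 outside), and immediate early genes by 0.08, -0.23 and 0.20 (rat 19 inside). On leaving out rat 35, the highest minus lowest deviation of the apoptosis, ferroptosis, heat shock and immediate early lists went from 0.90, 0.54, 0.83 and 0.42 to 0.23, 0.01, 0.50 and 0.20. Without rat 70 it was 0.56, 0.24 and 0.04 for the apoptosis, heat shock and immediate early lists, and without rat 19 it was 0.54 and 0.10 for heat shock and immediate early genes. The call of rat 70 for heat shock genes ended after rescaling to a common sum (-0.21, range 0.40) and with all detected members (-0.16, range 0.23), and that for apoptosis at a mean FPKM of 5 or more (-0.34). Immediate early genes had the opposite sign in rats 35 and 70 at that minimum (0.19 and -0.19, both inside), and rat 35 was also inside with a pseudocount of 0.1 (-0.24), while rat 19 was outside with all detected members (0.16).

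**Figure D3:**
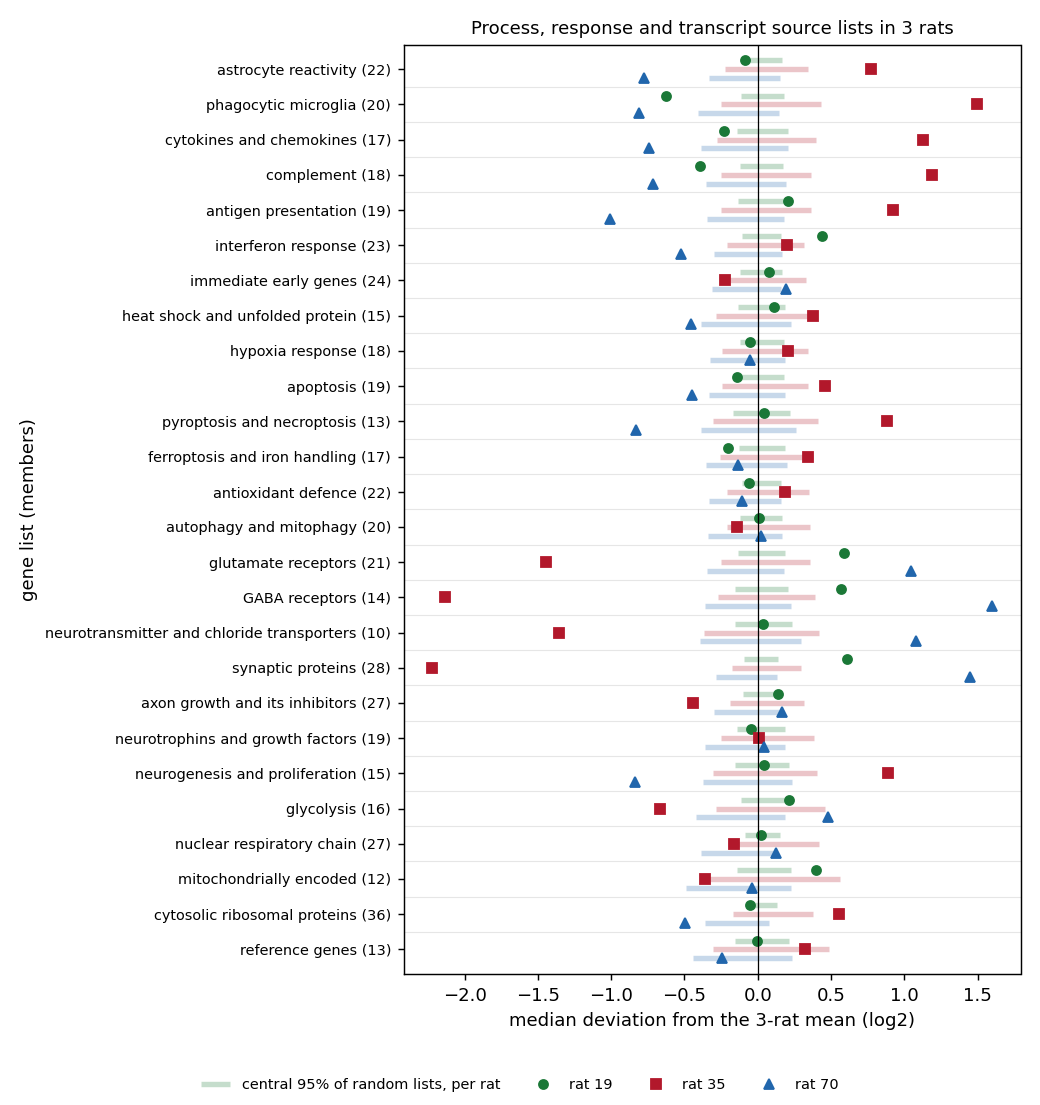
Deviation of the process, response and transcript source lists from the 3-rat mean, with points and pale lines as in the plot of cell type lists. Synaptic proteins (-2.22) and GABA receptors (-2.14) have their lowest values in rat 35, phagocytic microglia (1.499) and complement (1.19) their highest, and the 3 rats lie together for neurotrophins and growth factors.

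Across all genes, the distance between rats was large. Of 45 lists with enough members, 37 had at least 1 rat outside the random lists, and 87 of 135 list values were outside. The median SD over 14134 genes was 0.45 (log2, n = 3), and 6008 genes (42.5%) differed by more than 2-fold between their highest and lowest rat. Across genes, which are not independent replicates, Pearson correlations were 0.80 for rats 19 and 35, 0.93 for rats 19 and 70 and 0.71 for rats 35 and 70. Pairs of rats differed by more than 2-fold at 3685, 1548 and 5227 genes in the same order. Of the 6008 genes, rat 35 was the rat farthest from the other 2 in 4069 (67.7%), rat 70 in 1517 and rat 19 in 422. Leaving out rat 35 gave a median SD of 0.27, a correlation of 0.92 and 1549 genes over 2-fold apart, and without rat 70 that number was 3672.

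Mitochondrial transcripts were the most abundant. Of the 10 genes with the highest mean, 9 were mitochondrial, led by Mt-atp8 (22075 ± 6666 FPKM, SD, n = 3) and Mt-co1 (20075 ± 5096), and the other was Apoe (4060 ± 2927). Mitochondrial genes took 31.7%, 19.0% and 26.2% of the summed FPKM, and the 50 most abundant genes 38.7%, 31.8% and 33.5%. The 20 named genes with the largest SD were lowest in rat 35 for 16 and highest there for 4. Those 4 were S100a9, the macrophage metalloelastase gene Mmp12 (9.05, 196 and 3.55), the macrophage complement receptor gene Vsig4 (0.05, 47.5 and 6.13) and Fcrl2 (44.0, 530 and 12.2). The largest SD belonged to Ttr, which encodes the thyroid hormone carrier transthyretin (chromosome 18, 15532963 to 15540177), at 33.1, 0.17 and 362. Among the others were the neuropeptide gene Cck (172, 4.68 and 131), the neurofilament gene Nefl (60.8, 3.40 and 208), Chgb (170, 3.65 and 194), Nptx1 (53.0, 1.52 and 117), Syn2 (98.9, 2.23 and 111), Eef1a2 (199, 8.34 and 332) and Glycam1 (1.09, 0.84 and 50.2).

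Ratios of gene pairs within a rat had SDs from 0.14 to 2.62 (log2). Gpx4, which protects from lipid peroxidation, exceeded Acsl4, which promotes it, by 2.88 ± 0.14 (log2, SD, n = 3). Gad1 and Gad2, both GABA-synthesising enzymes, differed by -0.14 ± 0.14 although each varied over 20-fold, with Gad2 at 28.0, 1.97 and 46.0, and by -0.06 without rat 70. Gfap exceeded Aldh1l1 by 7.08 ± 0.31, C3 was below C1qa by -4.11 ± 0.23, and the anti-apoptotic Bcl2 was below the pro-apoptotic Bax by -3.56 ± 0.42. The ratio of the chloride exporter Slc12a5 to the importer Slc12a2 was -0.50 ± 1.94, from values of 0.45, -2.72 and 0.79, and its mean was 0.62 without rat 35, -0.97 without rat 19 and -1.14 without rat 70. The myelin gene Mbp exceeded Snap25 by 3.70 ± 2.62 (2.19 without rat 35), Hk1 exceeded Hk2 by 2.61 ± 1.75 and Slc17a7 exceeded Slc17a6 by 4.76 ± 1.85. Pvalb against Sst gave -1.39 ± 2.09, with -3.45, -1.45 and 0.73 in the rats, and a mean of -0.36 without rat 19 and -2.45 without rat 70.

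Other pairs lay between these. Gria2 exceeded Gria1 by 1.20 ± 0.73, Slc1a2 exceeded Slc1a3 by 0.67 ± 0.70 (0.28 without rat 70), Ntrk2 exceeded Ngfr by 4.12 ± 1.56 and Ldhb exceeded Ldha by 0.96 ± 0.93 (0.49 without rat 70). The homeostatic microglia gene P2ry12 was below the phagocytic marker Cd68 by -1.11 ± 0.79 (-0.66 without rat 35). No common direction was seen for Grin2a against Grin2b (0.24 ± 0.83, with 0.59 without rat 19 and -0.22 without rat 70), Bcl2l1 against Bax (-0.66 ± 0.69, with -0.33 without rat 19 and -1.02 without rat 70) or Rtn4 against Gap43 (-0.31 ± 1.54, with 0.48 without rat 19 and -1.06 without rat 35). In all, 13 of 18 pairs had the same sign in the 3 rats, 9 with the first gene higher and 4 with the second. These 13 had p = 0.25 in the exact sign-flip permutation test (Benjamini-Hochberg adjusted 0.35), the smallest value that 3 rats allow, so no ratio could pass 0.05.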

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

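Among list deviations called outside, those of immediate early genes reversed at a mean FPKM of 5 or more, to 0.19 in rat 35 and -0.19 in rat 70, where fewer genes enter; no other called deviation changed sign under another scaling, pseudocount or minimum. Of 87 called values, 85, 87, 86 and 81 stayed outside after rescaling to a common sum, after median-of-ratios scaling, with a pseudocount of 0.1 and with no minimum, and 73 of the 79 that could be computed at a minimum of 5. In 10 cases a value inside came to lie outside, among them ependyma in rat 35 under 3 settings. With 1 rat left out the other 2 deviate equally and oppositely, so only ranges are given there. The ratios of Slc12a5 to Slc12a2, Grin2a to Grin2b and Rtn4 to Gap43, which had no common sign, took the other sign on leaving out 1 rat. Of 45 list ranges, 34 moved by more than their spread without rat 35, 11 without rat 70, 4 without rat 19 and at most 5 under any other setting. Of 47 list levels, 27 did so after rescaling to a sum of 1000000, which raises all levels, 10 with a pseudocount of 0.1 and at most 3 under any other setting, and of 72 pair ratios 1 did. An FPKM minimum of 5 left 8250 expressed genes and a lowest correlation of 0.57, against 0.85 with no minimum, since the minimum decides which genes enter. A pseudocount of 0.1 took the Bcl2 to Bax ratio to -4.16, because Bcl2 lay near 1 FPKM. Without mitochondrial genes the 50 most abundant genes took 14.4% of the FPKM. Leaving out each rat in turn gave a median SD of 0.27 to 0.51, a lowest correlation of 0.70 to 0.92, 1549 to 5231 genes over 2-fold apart and 26 to 31 lists with a rat outside, and the extreme nearest to agreement always came without rat 35. With all detected members in place of those at a mean FPKM of 1, the hippocampal range was 0.11 in place of 2.36. No paired analysis was possible because there is 1 group. At 16 fragments per FPKM on a gene of 1 kb, values under 0.2 FPKM rest on a few fragments.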

Other observations

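A few further genes, chosen after their values were seen, differed widely between the rats. The interferon-induced gene Ifit1 was at 16.7, 0.41 and 0.06 FPKM in rats 19, 35 and 70. Class I and class II histocompatibility genes were low in rat 70, with RT1-A1 at 5.73, 4.83 and 0.40 and RT1-Ba at 8.60, 18.5 and 0.54. Shox2 and Lhx9, homeobox genes known from thalamic neurons, were found in rat 70 and hardly elsewhere, with Shox2 at 0.08, 0 and 16.5 and Lhx9 listed at 0 in rats 19 and 35 and at 5.90 in rat 70. Other homeobox genes were not looked at as a group, whereas lists of thalamus markers were. Hpca, which encodes the calcium sensor hippocalcin, was at 61.6, 19.9 and 529. The radial glia gene Fabp7 (763, 280 and 118), the matrix gene Tnc (29.1, 18.0 and 2.92), the Notch target Hes5 (11.5, 1.64 and 1.05), Marcks (128, 85.4 and 23.7) and Marcksl1 (205, 107 and 51.4) were highest in rat 19 and lowest in rat 70.

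The tests of scaling, gene length, the glial lists, the meninges and the choroid plexus were chosen after the result was seen; those of the 5 further lists were set out before their members' values were looked at.

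Rat 35 combined low neuron lists with high phagocyte and collagen lists. Library scaling, which moves all genes of a library in one direction, is argued against, since in rat 35 the pan-neuronal list lay at -2.42 (log2, bootstrap interval -3.13 to -2.29) and phagocytic microglia at 1.499 (1.33 to 1.90); so is loss of RNA from long transcripts, since the 37 pan-neuronal and synaptic genes deviated by -2.30 and random lists matched on expression and recovered transcript length lay between -0.21 and 0.22. Fewer neurons alone, with the transcripts of each glial cell unchanged, would raise all glial lists alike. In rat 35, however, microglia lay 1.79 above astrocytes (1.49 to 2.29, an interval over genes of 1 library). The lists cannot separate a change in glial cell numbers from a change in transcripts per cell. Meningeal tissue as a source of the collagen genes cannot be told apart from a scar, because the meninges list lay at 0.95 in rat 35 and pericytes at 0.58, yet 3 of 12 meningeal genes, among them the most abundant, Ptgds (1193, 1152 and 776 in rats 19, 35 and 70), were no higher there than in rat 19. A greater loss of neurons with a gathering of phagocytes, with or without scar-forming cells, may account for the rest of the pattern; this is a hypothesis that was not tested, since all 3 rats carry one label and no control was analysed, and a different position of the piece relative to the injury or a wrong label stays open.

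Rat 70 had high values of single thalamic and hippocampal genes. A further list of 12 thalamus markers, none in another list and 8 of them at 1 FPKM or more in all rats, was higher in rat 70 than in rat 19 by a median of 1.25 (log2), beyond the random lists (-0.48 to 0.28), with 10 of 12 genes in that direction, among them Plekhg1 (5.38, 9.82 and 21.9 in rats 19, 35 and 70) and Ntng1 (6.81, 0.74 and 25.9) but not the most abundant, Inf2 (18.8, 40.5 and 18.2). Most of the list, such as Plekhg1, Amotl1 (3.56, 9.69 and 7.85) and Plcb4 (3.34, 7.51 and 13.8), was also higher in rat 35 than in rat 19. Ntng1, Nexn, Cacna1g and Pcp4l1 were lower there. A further list of 10 hippocampus markers, 8 of them at 1 FPKM or more in all rats, differed by 0.35, just beyond its random range (-0.50 to 0.32), with Ociad2 (21.3, 11.2 and 28.3) and C1ql3 (27.9, 5.77 and 22.4) as the most abundant, while 8 cortical pyramidal markers gave -0.33. Tissue from the thalamus in the piece from rat 70 is therefore a candidate explanation, as a hypothesis. The first thalamic list, however, lay inside its random range. For the thalamus and the hippocampus alike, the random lists were matched on expression only, so neither further list can decide the source. List deviations of pan-neuronal markers (0.98 and 1.88) and synaptic proteins (0.61 and 1.45) were also higher in rat 70 than in rat 19. Those of inhibitory markers were not in the main setting (0.87 and 0.44). They were higher in rat 70 with a pseudocount of 0.1 (1.15 and 1.31) and at a mean FPKM of 5 or more (0.92 and 1.26). The first hippocampal list lay inside its random range with all detected members. Choroid plexus as the source of Ttr cannot be told apart from other sources. Of the 12 other markers, 4 followed the order of Ttr, against 2.0 if all orders of the rats were equally likely. Pan-neuronal and synaptic lists had that order too, so equal likelihood cannot be assumed. Only 8 of the 12 markers reached a mean FPKM of 1.

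Fabp7, Tnc, Hes5, Marcks and Marcksl1 are genes of immature neural tissue and of reactive glia. A list of 12 immature-neuron genes, 9 of them at 1 FPKM or more in all rats, was higher in rat 19 than in rat 70 by a median of 0.58 (log2), beyond the random lists (-0.23 to 0.46), but 5 of the 12 went the other way, and the most abundant were Nnat (428, 137 and 154) and Stmn1 (179, 61.3 and 125). A list of 11 genes of progenitor-like astroglia, all 11 at 1 FPKM or more in each rat and led by Id3 (169, 196 and 73.4), differed by 0.40, inside its random range (-0.30 to 0.50), although 9 of 11 were higher in rat 19, so that this source cannot be told apart from chance. The list cannot assign this difference to neurons. Tubb2b (115, 45.9 and 45.6), Cd24 (56.5, 22.7 and 22.8) and Mdk (43.9, 150 and 25.8) were higher in rat 19 than in rat 70. In rat 35, where neuron lists were lowest, they were about as high as in rat 70 or higher, although Nnat and Stmn1 were lower there. Less mature neurons in rat 19 therefore stay a hypothesis that the list does not decide. The other tissue in rat 70 stays open as another part of the pattern. So does the tissue content of rat 19, which was not tested. Its striatal list lay outside the random range (0.997, against -0.14 in rat 70). No biological explanation that the design names was tested, since the labels give the 3 rats the same sex, strain and time.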
